A study of Mus musculus with 2 samples.

How the data were processed

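RNA from sorted nephron progenitor cells of WT and KO mouse embryos at embryonic day 15.5 was sequenced, in 1 library per genotype. Per the submitters' processing notes, the software named is CASAVA 1.8, Novoalign 2.08.02 and FastQC, and the genome builds GRCm38 and mm10, with no role or order given. The counting rules, the strand used and the treatment of reads that align to several places are not given in the sources used here.

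Per the file headers, the authors deposited a read density for each library, a p-value, a corrected p-value and a fold change for KO against WT. The deposited read density behaves as RPKM, reads scaled by gene length and library depth, a reading taken from the values since the header says only density. Of 171 genes at 0 in KO and 75 genes at 0 in WT, 150 and 70 had fold changes that were whole multiples of a single step, within 0.01 of a read. Density times gene length per read gave the same constant, within 0.5%, for 100 of the 149 such genes with a gene model in WT and 48 of 67 in KO. The implied depths of about 91200000 reads in WT and about 85600000 reads in KO rest on these genes, so read estimates and intervals are approximate. The deposited p-value of these genes matched, within 2%, a formula on the 2 depths and the gene's inferred reads in 146 genes for WT and 70 for KO. The deposited p-value was 0 for 1998 genes. The largest corrected p-value in the table is 0.0499827, so the table holds only genes that passed a corrected p-value of 0.05 in the authors' comparison, and genes outside it are not analysed here. The product of corrected p-value and rank over p-value had a median of 38088, the number of genes that a Benjamini-Hochberg correction would have covered. The deposited fold ratio is the density ratio times 1.04, a further library scaling by the authors of 0.057 on the log2 scale. The deposited signed fold change, a score that is negative where KO was lower, carries the same scaling, and against a density of 0 it is set against a small constant, so no fold is printed for such genes.

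The table has 10617 distinct symbols, and 8 symbols on more than 1 row were represented by the row with the highest mean density. The main measure was log2(KO + 1) minus log2(WT + 1) on the deposited densities, so folds of genes with low densities are understated. Genes in the upper 50% by mean density, at or over 7.30 RPKM, were taken as over the floor. A difference of 1.5-fold was the size rule, with no test and no p-value across genes, since 1 library per group gives no replicate spread. Exact (Clopper-Pearson) 95% intervals of the ratio used reads estimated from density, gene length and implied depth, and they cover counting error only.

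The 37 gene lists, the floor, the size rule, the named gene rule and all alternatives but the last 2 were fixed before the data were examined. They cover p53 targets, the nephron progenitor state, early nephron differentiation, podocytes and tubules, glycolysis, oxidative phosphorylation, the citric acid cycle, fatty acid oxidation, the pentose phosphate pathway, antioxidant enzymes, mitochondrially encoded genes, cell adhesion, extracellular matrix, polarity, Eph receptors and ephrins, cell cycle phases, DNA replication, replication-dependent histones, apoptosis, Wnt, FGF, BMP and TGF-beta, YAP and TAZ, interferon, hypoxia and unfolded protein responses, tissue dissociation stress, ribosomal proteins, sex-linked genes, imprinted genes, and markers of ureteric bud, stroma, endothelium, erythroid cells, leukocytes, neural cells and muscle. A list's median over genes past the floor was set among 10000 random lists of the same size, drawn from the listed genes and matched on mean density in 20 bins, as a description of these libraries. A list was said to stand apart at a percentile at or under 2.5 or at or over 97.5. Of 29 lists with at least 3 genes over the floor, 10 stood apart low and 3 high.

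The named genes were Trp53, Six2 and Cited1, the 6 highest and 6 lowest genes over the floor that are not predicted genes, small non-coding RNAs or pseudogenes, the 3 members with the largest difference in the direction of the median from each list that stood apart, and 2 from each marker or technical list that did. One gene that this rule names is not reported here. Other genes named were chosen after their values were seen, as were the members named of lists under the floor.

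GC content and length came from gene models of GENCODE vM21, which cover 10515 listed genes; 10511 of them overlap the deposited coordinates. In the correction for GC content and length, the median difference of genes in the same of 10 GC bins and 4 length bins was subtracted and the median of all genes added back. The scripts were tested on simulated data. Of 94 genes over the floor given a 2-fold change in simulated reads, 94 were called at 1.5-fold, against 0 of 95 given a 1.25-fold change and 0 of 5030 unchanged genes. These simulated reads held counting error only, with no spread between embryos and no trend with GC content. They therefore give no rate of false calls for the size rule in real libraries. Of 500 random lists of 15 genes, 33 stood apart, and when their genes were moved by -0.15, 337 of 500 stood apart low. The alternatives tried were other scalings, pseudocounts of 0.25 and 4, no floor, a floor at the 75th percentile, the mean over rows of a symbol, a 2-fold size rule, random lists not matched on density, the scaling of the authors' fold changes and the correction for GC content and length. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.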

Results

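Messenger RNA was profiled in nephron progenitor cells, the Six2-expressing cap mesenchyme cells that give rise to the epithelium of the kidney's filtering units. The cells were sorted by flow cytometry from mouse kidneys at embryonic day 15.5, using a Six2 transgene that carries both Cre recombinase and GFP. The wild-type group (WT) had intact p53, and the knockout group (KO) carried floxed alleles of Trp53, the gene for p53, which Cre deletes in these cells. There was 1 library per group. The deposited table lists 10627 genes with a read density in RPKM for each library. The steps between the fold changes of genes at 0 in 1 library correspond to a depth of about 91200000 reads in the WT library and about 85600000 reads in the KO library. Over the 5263 genes above the density floor that have a gene model, the median gene had an estimated 8165 reads in WT and 7532 in KO, so counting error is small for most values given here.

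The comparison of KO with WT asks how loss of p53 alters gene expression in cells that must both renew themselves and supply the forming nephrons. Trp53 itself was lower in the KO library. Its density was 33.9 RPKM in WT and 5.38 RPKM in KO, a ratio of 0.158 (95% exact interval 0.151 to 0.166, counting error only). In the authors' deposited table Trp53 was 6.06-fold lower in KO. Trp53 (ENSMUSG00000059552) lies on chromosome 11 from 69580359 to 69591873 on the plus strand of GRCm38, and the density covers its whole gene model, so reads from exons outside the deleted part count too. Six2, the transcription factor that keeps these cells undifferentiated (ENSMUSG00000024134, chromosome 17, 85684268 to 85688274, minus strand), had similar densities of 482 RPKM in WT and 509 RPKM in KO. Its log2 difference was 0.078, and 0.20 after a correction for GC content and gene length. Cells of both libraries were sorted on a Six2 transgene, so the sort itself selects for Six2 expression. Cited1, which marks the least committed progenitors (ENSMUSG00000051159, chromosome X, 102247381 to 102252181, minus strand), was lower in KO, at 16.1 against 23.6 RPKM, a log2 difference of -0.53.

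Most genes differed little in size. Of 5309 genes over the floor, 35 were at least 1.5-fold higher in KO and 128 at least 1.5-fold lower, while 96.9% lay within 1.5-fold. At 2-fold, 10 were higher and 46 lower. Centring both libraries on their median difference gave 54 higher and 100 lower at 1.5-fold, and the scaling behind the authors' fold changes 49 and 104. Apart from predicted genes, the highest in KO included Xist, the non-coding RNA that silences one X chromosome in female cells, at 15.7 RPKM in WT and 70.1 in KO. Trim25, a ubiquitin ligase, was at 6.01 RPKM in WT and 12.5 in KO, and the metalloprotease gene Adamts17 at 7.44 and 14.5 RPKM. The long non-coding RNA AC122881.1 was at 124 RPKM in WT and 456 in KO, and Hddc3 at 18.8 and 32.3 RPKM. Fau, a ribosomal protein fusion gene, was at 3.25 and 13.5 RPKM, a value that is uncertain because processed copies of the gene can take its reads. The lowest in KO were the adult globin genes. Hbb-b1 had 237 RPKM in WT and 9.69 in KO, and Hba-a1 had 133 and 4.89, while Hbb-b2 and Hba-a2 showed log2 differences of -4.74 and -4.41. The globin copies are nearly identical, so their individual values are uncertain. Fxyd2, a regulator of the sodium pump in tubules, was also among the 6 lowest, at 18.9 RPKM in WT and 2.25 in KO.

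**Figure D1:**
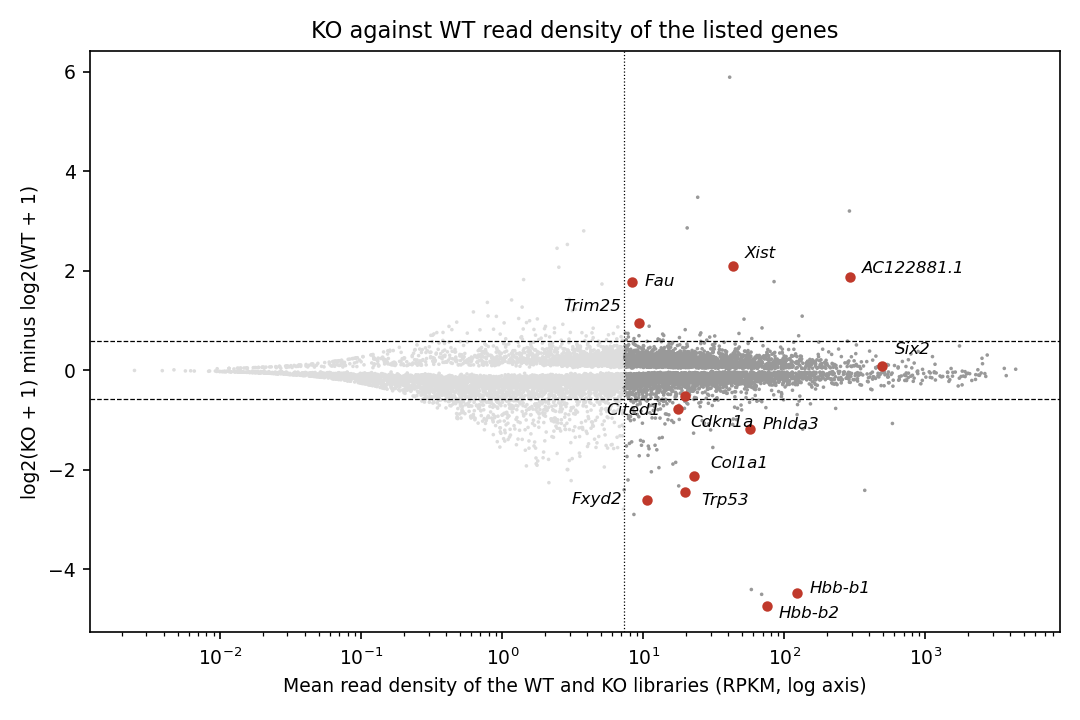
Each point is a listed gene. The x axis is the mean read density of both libraries (RPKM, log axis) and the y axis is log2(KO + 1) minus log2(WT + 1). The dotted line is the density floor at 7.30 RPKM, the dashed lines mark 1.5-fold, and the empty band around 0 arises because the table holds only genes with a corrected p-value under 0.05; Trp53 sits at -2.45 and Six2 at 0.078.

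Genes that p53 activates were lower as a group. Of 16 listed targets over the floor, 14 were lower in KO and 5 were at least 1.5-fold lower, with a median log2 difference of -0.19 at percentile 0.21 among 10000 random lists of matched density. Of all 29 listed targets, 26 were lower in the authors' deposited table. The target list was fixed at 42 names, and only these 29 are in that table, which holds only genes that passed the authors' corrected p-value limit. The direction of the absent names is not known, so the share lower among all 42 cannot be given. Markers of erythroid cells, leukocytes, endothelium and stroma were lower in the same library, 66 of 68 in all, against 63.9% of all listed genes. Phlda3, an inhibitor of the kinase Akt, was at 79.8 RPKM in WT and 34.6 in KO, a log2 difference of -1.18. Cdkn1a, the cell cycle inhibitor p21, was at 22.5 and 12.7 RPKM, and Ccng1, cyclin G1, at 15.3 and 8.79. The 3 listed targets that were higher in KO were Plk2 (17.7 and 22.5 RPKM), Gadd45a (7.57 and 8.42 RPKM) and, under the floor, Rrm2b (1.56 and 1.94 RPKM), named after their values were seen.

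Genes of the nephron progenitor state were split in direction. Of 22 over the floor, 13 were higher and 9 lower in KO and none reached 1.5-fold. Their median of 0.089 stood at percentile 97.95 among matched random lists. Itga8, an integrin of the cap mesenchyme that is needed for kidney outgrowth, was at 20.05 RPKM in WT and 25.7 in KO. The transcriptional regulator Eya1 was at 66.8 and 84.1 RPKM, and its relative Eya4 at 14.98 and 18.7 RPKM. Larger differences went the other way in 2 members over the floor. These were Cited1, with a log2 difference of -0.53, and Hoxc11 (25.1 and 17.5 RPKM), with one of -0.50. After a correction for GC content and gene length, the list median was 0.012 at percentile 98.88, and the log2 differences of Itga8, Eya1 and Eya4 went from 0.35, 0.33 and 0.30 to 0.11, 0.15 and 0.068. With random lists that were not matched on density, the percentile was 92.83, inside the central range. The list of early nephron genes, such as those of the renal vesicle, had a median of 0.12 over 10 genes at percentile 94.46, and of -0.0075 after the same correction. Of these 10, 6 were higher in KO, Bmp2 (9.95 and 15.6 RPKM) by at least 1.5-fold, and 4 were lower, Lfng (11.4 and 5.87 RPKM) and Osr2 (15.3 and 8.27 RPKM) by at least 1.5-fold. Including listed genes under the floor reversed it to -0.26 over 21 genes at percentile 0.32, with 15 of the 21 lower in the authors' deposited table, such as Pou3f3 at 4.16 and 1.93 RPKM.

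Genes of energy metabolism were lower in KO by small amounts. All 57 listed subunits of the respiratory chain and ATP synthase over the floor were lower, with a median of -0.17 at percentile 0. The median of all genes over the floor was itself -0.072. When both libraries were centred on that median difference, 51 of the 57 were lower, with a median of -0.098. Ndufa12 of complex I was at 15.6 RPKM in WT and 7.51 in KO, Cox6b2 of complex IV at 12.1 and 6.04, and Ndufs5 of complex I at 17.1 and 10.7. Of 15 glycolysis genes over the floor, 14 were lower, with a median of -0.23 at percentile 0.08, or 12 with a median of -0.16 after centring. Among them Tpi1 (152 and 105 RPKM), Ldhb (73.1 and 51.1) and Ldha (189 and 153), which code for triosephosphate isomerase and the subunits of lactate dehydrogenase, differed most. The fatty acid oxidation list had a median of -0.18 at percentile 1.83, with Acadm at 12.1 and 9.08 RPKM, Acads at 26.4 and 22.2, and Eci1 at 21.7 and 18.6. Correction for GC content and gene length took that list to percentile 10.6 and the log2 difference of Acads from -0.24 to -0.11, and the list did not stand apart without the floor (percentile 6.43) or with a floor at the 75th percentile of density (20.6) either. Citric acid cycle genes (median -0.084, percentile 40.02), pentose phosphate genes (median -0.14, percentile 19.19) and antioxidant enzymes (median -0.15, percentile 3.08) did not stand apart. The antioxidant list did so without the floor (percentile 0.25), with a floor at the 75th percentile of density (2.16) and after the correction (0.805). In the same comparison, erythroid, stromal, endothelial and leukocyte markers were also lower in KO.

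**Figure D2:**
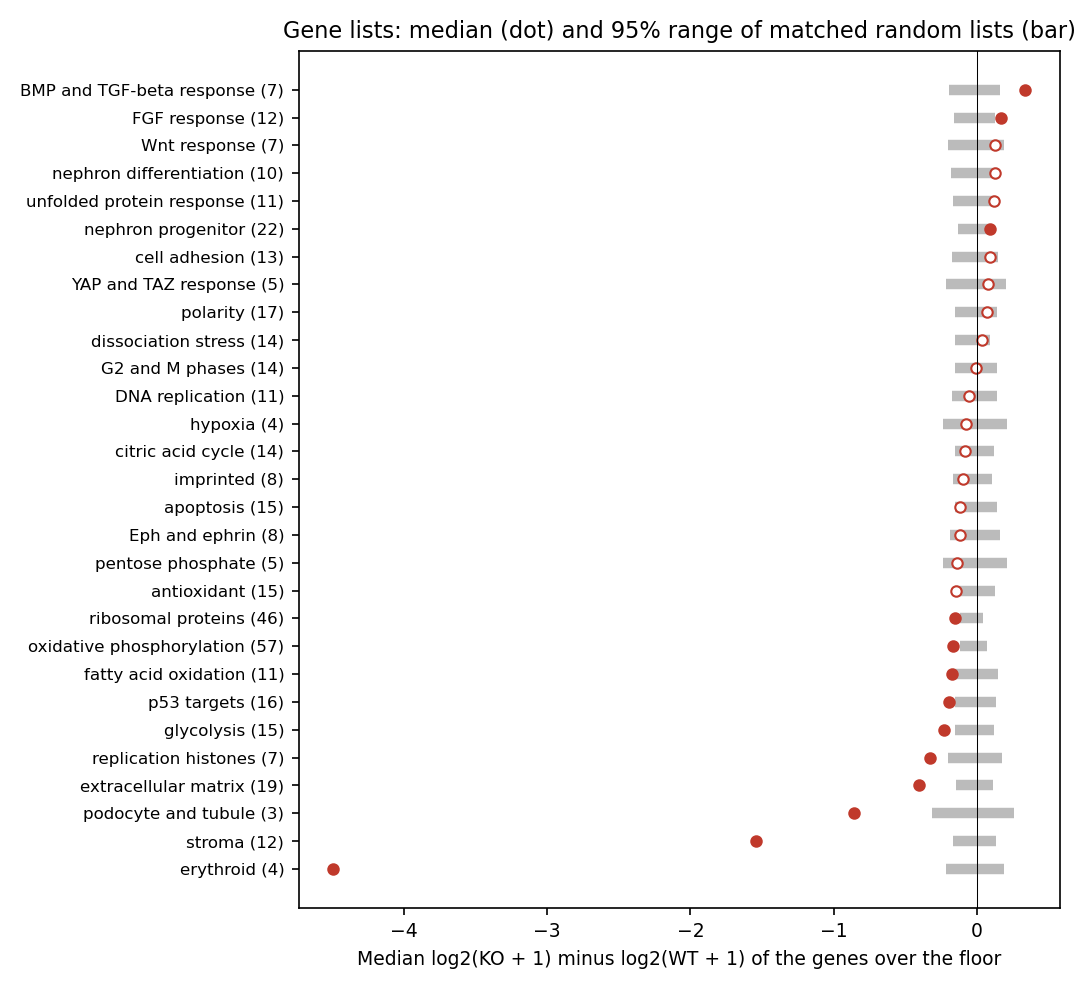
Dots are the median log2(KO + 1) minus log2(WT + 1) of each list's genes over the floor, with the number of genes in brackets, and grey bars are the 95% range of matched random lists. Filled dots stand apart. The lowest are erythroid (-4.49, the 4 adult globin genes) and stroma (-1.54), and the highest is the BMP and TGF-beta response (0.33).

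Most response genes of BMP, TGF-beta and FGF were higher by small amounts, and none of those over the floor reached 1.5-fold on the main measure. The 7 BMP and TGF-beta response genes over the floor had a median of 0.33 at percentile 99.99, with 6 of 7 higher. Smad7, an inhibitor of that pathway, was at 11.5 RPKM in WT and 15.4 in KO, Skil at 9.91 and 13.2, and Id2 at 180 and 232. Of 12 FGF response genes, 10 were higher, with a median of 0.17 at percentile 99.48. The phosphatase gene Dusp5 was at 30.1 and 44.8 RPKM, and the feedback inhibitors Spry2 at 38.2 and 51.7 and Spred1 at 20.4 and 26.3. After the correction for GC content and length, the BMP and TGF-beta median was 0.19 at percentile 99.9 and the FGF median 0.14 at percentile 100. The log2 differences of Skil, Id2 and Spred1 went from 0.38, 0.37 and 0.35 to 0.095, 0.21 and 0.069, while those of Smad7, Dusp5 and Spry2 went from 0.39, 0.56 and 0.42 to 0.45, 0.64 and 0.41. Under the same correction, the immediate early and heat shock genes induced by tissue dissociation also stood apart high, at percentile 99.97. The cause of these shifts was not tested. Cell adhesion genes, the cadherins, protocadherins and integrins, had a median of 0.087 over 13 genes at percentile 80.1 and did not stand apart. With the genes under the floor included, their median was -0.068 and stood apart high, at percentile 99.61 among lists of matched density. After the correction, the median over the floor was -0.088 at percentile 42.2.

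Genes of the extracellular matrix were lower in KO, with 15 of 19 lower, 7 at least 1.5-fold lower and a median of -0.41 at percentile 0. Col1a1 was at 37.8 RPKM in WT and 7.82 in KO, Col3a1 at 26.1 and 6.32, and Col1a2 at 17.1 and 4.51. The stromal marker list holds 4 of the matrix genes. Without them, the median was -0.34 over 16 genes at percentile 0. Of 7 replication-dependent histone genes over the floor, 5 were lower, with a median of -0.33 at percentile 0.08. With a floor at the 75th percentile of density the median was -0.12 over 4 genes at percentile 24.66, and of all 18 listed histone genes 7 were higher in the authors' deposited table. Hist1h4i was at 58.9 and 27.1 RPKM, Hist1h2bj at 17.7 and 8.57, and Hist1h3c at 17.1 and 12.8, values that are uncertain because histone genes of a family resemble one another. Ribosomal protein genes had a median of -0.15 over 46 genes at percentile 0.02, led by Rpl29 (791 and 375 RPKM) and Rpl3 (153 and 94.4). The list median and both genes are uncertain for the same reason, since ribosomal protein genes have many processed copies.

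Markers of erythroid cells, leukocytes, endothelium and stroma, other cell types that the sort could hold, were mostly lower in KO. Neural and muscle markers were less uniform, with 4 of 7 and 3 of 4 lower, where 63.9% of all listed genes were lower. All 12 listed erythroid, all 14 leukocyte and all 20 endothelial genes were lower, as were 20 of 22 stromal genes. The stromal list had a median of -1.54 over 12 genes at percentile 0, with Ntn1 at 18.96 RPKM in WT and 3.84 in KO. The erythroid list had a median of -4.49 over 4 genes at percentile 0. These 4 are the adult globin genes, whose near-identical copies can share reads, so they are not 4 separate measures. Over all 12 listed erythroid genes the median was -0.86 at percentile 0. Of the stromal list, Aldh1a2 was at 272 RPKM in WT and 286 in KO and Meis2 at 23.4 and 29.5, while Tcf21 was at 79.5 and 51.9 and Foxd1 at 63.7 and 43.1. Leukocyte genes were low in both libraries, such as C1qb at 4.25 and 0.644 RPKM and Lyz2 at 2.70 and 0.212. Most endothelial genes were low too, such as Cdh5 at 1.82 and 0.313 RPKM. Of the 20 endothelial genes, 2 lay over the floor, both lower in KO and 1 of them by at least 1.5-fold. Over all listed genes, the leukocyte median was -0.71 at percentile 0 and the endothelial median -0.42 at percentile 0.02. Of the podocyte and tubule genes, all 17 were lower in the authors' deposited table. The 3 over the floor had a median of -0.86 at percentile 0.055, Fxyd2 among them with Cldn5 (14.6 and 7.61 RPKM) and Epcam (10.6 and 7.01 RPKM). All 14 listed ureteric bud genes were lower too, with a median over all listed genes of -0.28 at percentile 11.3.

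**Figure D3:**
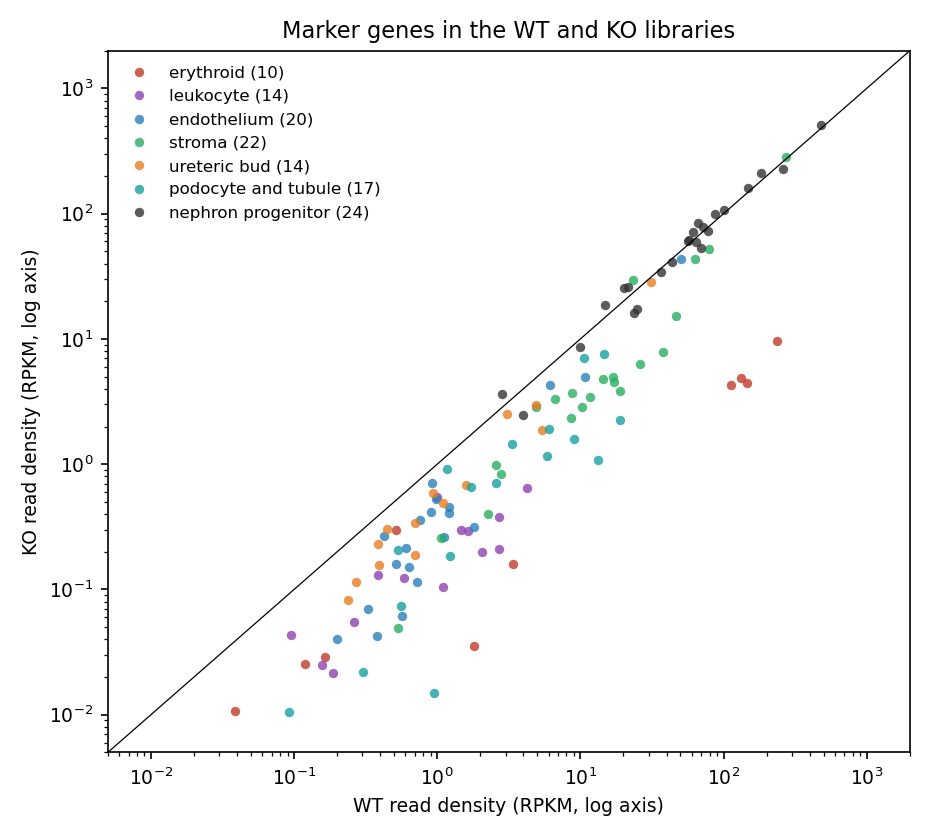
Each point is a marker gene above 0 in both libraries, with its WT density on the x axis and its KO density on the y axis (RPKM, log axes), colored by list, and the line marks equal density. Nephron progenitor genes lie near the line, Six2 at 482 and 509 RPKM, while the globin genes lie far under it, Hbb-b1 at 237 and 9.69 RPKM.

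The remaining lists over the floor did not stand apart on the deposited densities. Their percentiles were 60.48 for genes of the G2 and M phases, 58.37 for DNA replication, 12.95 for BCL2 family members and caspases, 88.42 for Wnt response, 72.31 for YAP and TAZ response, 37.48 for hypoxia, 96.93 for the unfolded protein response, 68.78 for polarity genes, 18.67 for Eph receptors and ephrins, 28.39 for imprinted genes and 89.01 for the immediate early and heat shock genes induced by tissue dissociation. After the correction for GC content and length, the dissociation list stood apart high (median 0.12, percentile 99.97), as did the Wnt response (percentile 99.65) and the unfolded protein response (percentile 99.6, and 98.2 without the floor). Without the floor, the imprinted list stood apart low, with a median of -0.40 at percentile 0. The interferon, neural and muscle lists had fewer than 3 genes over the floor; over all listed genes their medians were -0.28 (percentile 9.19), -0.083 (percentile 88.73) and -0.18 (percentile 40.03). The 5 sex-linked genes, Xist and 4 genes of the Y chromosome, had a median of -0.49 at percentile 1.03, with Xist higher and the other 4 lower in KO. No mitochondrially encoded gene was listed.

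The libraries also differed with base composition. Across 5263 genes over the floor, Spearman's rho between GC content and the log2 difference was -0.53, and between gene length and the log2 difference 0.34, where genes are not independent replicates. With the genes in 5 equal groups by GC content, the median was 0.17 in the lowest group and -0.15 in the highest. No difference here has a replicate check, counts within lists leave out members that did not pass the authors' p-value, and the p-values of the authors' deposited table compare the 2 libraries, not the genotypes.

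**Figure D4:**
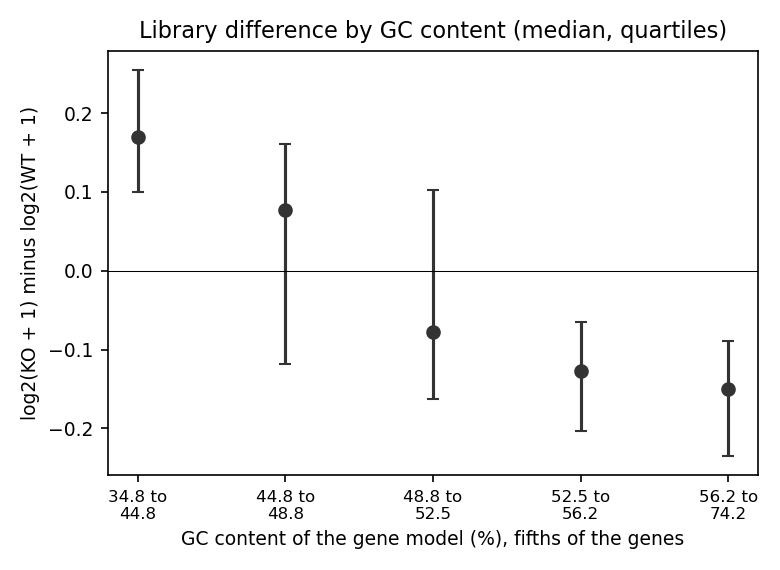
Genes over the floor are split into 5 equal groups by the GC content of their gene model (x axis, percent). Dots and bars are the median and quartiles of log2(KO + 1) minus log2(WT + 1), which is 0.17 in the lowest group and -0.15 in the highest.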

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

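The authors' scaling and the correction for GC content and length were chosen after seeing the data. Of 286 list medians under the alternatives, 257 kept their sign and their side of the limits, 8 came to stand apart and 5 no longer did, and 14 medians of lists that stood apart in neither setting changed sign. Under the 6 alternatives that alter the difference of a single gene, 140 of 276 differences of other named genes stayed within their counting interval and 136 moved beyond it, with no change of sign. The Trp53 difference of -2.45 stayed negative, at -2.38 when centred on the median, -2.60 with a pseudocount of 0.25 and -2.02 with one of 4. Of the main 35 genes at least 1.5-fold higher and 128 lower, centring on the median gave 54 higher and 100 lower, the authors' scaling 49 and 104, a pseudocount of 4 gave 22 higher, no filter on low density gave 101 and 583, a floor at the 75th percentile 17 and 42, and a 2-fold rule 10 and 46. The 2-fold counts follow from the stricter size. Without the filter, the 5308 genes under the floor added 66 higher and 455 lower, more than their number alone would give, and the cause was not tested there or for the other settings. These counts carry the pseudocount of 1, which shrinks differences at low densities. In the authors' deposited fold changes, 544 of all listed symbols were at least 1.5-fold higher and 2253 lower, against 63 and 119 over the floor. With no filter, the early nephron list reversed to -0.26 and stood apart low, at percentile 0.32. The cell adhesion median changed sign to -0.068, yet among random lists of matched density it stood apart high, at percentile 99.61. With no filter, 14 of the other lists stood apart, against 9. With random lists not matched on density, the nephron progenitor median of 0.089 no longer stood apart. The alternative of count-based size factors was not run because the values are not counts. No paired analysis was possible because each genotype has 1 library. Counting error is small at this depth, but the spread between embryos is not measured by any value here.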

Other observations

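The tests in this part were all chosen after the results they measure were seen. Clustered protocadherin beta genes, cell surface proteins encoded in 1 array, were higher in KO for 15 of 16 listed members, although none reached the floor. Pcdhb11 was at 1.31 RPKM in WT and 2.75 in KO and Pcdhb6 at 1.18 and 2.03, while Pcdhb4 was lower, at 1.04 and 0.804. These and the next families were picked after their values were seen and were not tested for enrichment. Lower in KO were 29 of 34 listed collagens, 13 of 14 claudins, which form tight junctions, all 10 UDP glucuronosyltransferases and all 10 Ccl chemokines, where 63.9% of all listed genes were lower. No UDP glucuronosyltransferase or Ccl chemokine reached the floor, and 71.9% of genes under it were lower in the authors' fold changes. Of imprinted genes, the growth inhibitor Cdkn1c was at 291 RPKM in WT and 170 in KO and H19 at 2453 and 3026.

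Markers of erythroid cells, leukocytes, endothelium and stroma were lower in KO although sorting on Six2-driven GFP should remove these cells. One lower share of progenitors in the WT library, with all other types raised alike there, would give like density ratios. The types farthest apart, erythroid and ureteric bud, were picked from these values. Their median log2 density ratios differed by -3.40 and their quartiles did not overlap. Only 1 of the 14 ureteric bud markers lay over the floor, so this contrast cannot decide for or against such an even rise. A bias against low densities is argued against for the erythroid, leukocyte, endothelial and stromal markers, whose highest percentile among random lists of like density was 0.02. The ureteric bud markers, at percentile 11.31, could follow from it. More cells of these types in the WT library remain a possible explanation that these data cannot decide, since the share of their 68 markers lower in KO, 97.1%, is the pattern itself. An effect of p53 on how such cells enter the sort, or on expression of the same genes in progenitors, was not tested, and 12 of the 22 stromal genes lay over the density floor.

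Xist was higher in KO and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were each lower, at 8.64 and 5.85, 7.39 and 3.88, 3.14 and 1.94, and 1.33 and 0.857 RPKM. If each library pooled several embryos, which the labels do not state, a larger share of female embryos in the KO pool may explain this, and Xist with the median Y-linked gene implies 43.1% female cells in KO and 9.68% in WT. Any higher Xist with a lower Y-linked gene gives possible shares, so these values restate the pattern and add no support. The trend with GC content is argued against, since Xist kept a log2 difference of 1.802 after the correction for GC content and length. X-linked genes that escape silencing were also higher, with log2 differences of 0.56 for Ddx3x, 0.32 for Kdm5c and 0.27 for Eif2s3x, and of 0.29, 0.32 and 0.063 after the correction. An effect of genotype on the sex ratio of the embryos was not tested.

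The trend with GC content and length could produce small shifts of whole lists. After the correction, the p53 target list was at -0.27 (percentile 0.01, quartiles -0.55 to -0.08), glycolysis at -0.21 (percentile 0.08) and oxidative phosphorylation at -0.15 (percentile 0.02), so the trend is argued against as their whole source. The fatty acid oxidation list went from -0.18 (quartiles -0.21 to -0.13) to -0.13 (quartiles -0.25 to -0.05), inside the range of random lists. All 11 of its genes were lower after the correction, against 10 before, and the median of all genes over the floor was -0.072. The trend may be the source of its difference, in part or whole. The Zfp zinc finger genes, 142 of 199 higher in the authors' deposited table, went from 0.11 to -0.016, while the 8 SR splicing factor genes, all higher, went from 0.31 to 0.12 with quartiles of 0.056 to 0.14, which is 0.38 and then 0.19 above the median of all genes, so part of their difference followed the trend. A difference in cell makeup was not separated from an effect of p53 on metabolism, and no biological explanation was tested for these lists.

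Alleles carried along with the floxed Trp53 locus in this mixed strain could make neighbouring genes differ. Of 185 genes over the floor within 20 Mb of Trp53, 4 differed by at least 1.5-fold, namely Anxa6, Hic1, Ntn1 and Trim25. That share, 2.16% against 3.11% of genes on all other chromosomes, stood at percentile 32.2 among windows there. This argues against a broad effect on the neighbourhood, but it cannot exclude an effect on single genes such as Ntn1 or Trim25.

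Ribosomal protein pseudogenes give a view of shared reads. Of 50 listed copies, 2 were at least 2-fold higher and 3 at least 2-fold lower in the authors' deposited table. Rps13-ps1 was at 0.391 RPKM in WT and 81.4 in KO, and Rps2-ps13 at 85.3 and 182. The parent gene Rps2 was at 189 RPKM in WT and 117 in KO, and Rps13 was not listed. For Rpl3, at 153 RPKM in WT and 94.4 in KO, the copy Rpl3-ps1 was at 1502 and 1536 and Rpl3-ps2 at 39.8 and 26.8.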
